A study of Mus musculus with 12 samples.

How the data were processed

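Gene expression was measured on 12 Affymetrix mouse gene arrays, with 3 arrays in each of 4 groups. Mouse embryonic stem cells (ESC) carried either a scrambled control shRNA or an shRNA against Jarid1b, and neural progenitor cells (NPC) made from such cells carried the same 2 constructs. Per the labels' protocols, ESC were exposed to lentivirus for 16 h and put under puromycin selection 48 h after transduction. The labels name 1 Jarid1b shRNA construct. They do not say whether the replicates of a group came from separate transductions or cultures, so p-values measure only the spread between these arrays, which may be technical. Jarid1b is listed under its current symbol, Kdm5b.

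The deposited values are on the log2 scale, 1 value per probe set and array. Per the submitters' processing notes, affy, RMA and limma were used; their versions are not given in the sources used here. RMA corrects background, normalizes quantiles between arrays and summarizes probes, which compresses differences near the floor and the ceiling of the array. Array medians lay between 7.70 and 7.79. The genome build is not given in the sources used here and no coordinates are reported. The values come with no detection calls, so a gene near the floor cannot be told from an absent one, and the number of arrays limits the precision.

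Of 21212 probe sets, 18786 had 1 gene symbol in the platform annotation, 6 had several and 2420 were not listed and stay unnamed here. Symbols were compared through Entrez gene IDs with a RefSeq gene table of assembly GRCm38.p6, used only for names; 18775 of the listed probe sets matched and 0 symbols changed. Where a gene had several probe sets the one with the highest mean was used, which gave 18784 genes. Unnamed probe sets stayed in the fit and out of the adjustment for multiple tests.

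From these values, a group-means model was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with lmFit, contrasts.fit and eBayes at default settings, 8 residual degrees of freedom and 4.81 prior degrees of freedom. The contrasts were knockdown minus control in ESC, knockdown minus control in NPC, the difference of these effects (NPC minus ESC), and NPC minus ESC in control and in knockdown cells. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over 18784 genes, and a gene is said to have risen or fallen at an adjusted p under 0.05. Changes are log2 differences of group means with limma's standard error (SE). All tests were two-sided.

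Named genes were chosen by a rule fixed before the data were examined: Kdm5b, the 10 largest rises and 10 largest falls in each knockdown contrast whose groups did not overlap, the 8 largest each way in the other contrasts, passing over symbols of unnamed gene models, and up to 4 members with the smallest p of each list. Genes named beyond the rule are marked as chosen after their values were seen. The 28 gene lists, also fixed beforehand, held 552 entries of which 505 were measured. They were pluripotency, germ cell, neural progenitor, neuronal, glial, mesoderm, endoderm, trophoblast, fibroblast and mesenchyme, 2-cell-like, formative and primed, Hox, retinoic acid response, cell cycle, cell cycle inhibitors, p53 response, interferon response, H3K4 methylation enzymes, Polycomb, DNA methylation, imprinted, immediate early and heat shock, unfolded protein and amino acid response, apoptosis, cholesterol synthesis, glycolysis and hypoxia, Y-linked and Xist, and blood and immune genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance 1 way without comparing them with other genes.

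Alternatives were a replicate block, a filter on low values (13272 genes kept), an intensity trend with a robust prior, array weights, median centring, quantile normalization, the mean of a gene's probe sets, adjustment over all rows, the 6 arrays of a contrast alone, a threshold of 0.01, a 2-fold minimum and leaving out each array. A replicate block on the 6 control arrays was added after seeing the data. Replicate numbers come from the sample titles. Deviations from the group means of same-numbered control ESC and control NPC arrays correlated across genes at 0.265, 0.267 and 0.334. So the numbers were taken to pair the arrays of that contrast, which is read from the data. In no other contrast did all 3 pairs exceed 0.1. Same-numbered control ESC and knockdown NPC arrays, which form no contrast, gave -0.262, -0.176 and -0.123.

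Contrasts that share arrays also share chance values; 100 simulations of unchanged groups gave the correlation and covariance to set beside the observed ones. The steps were tested on simulated data for 18784 genes with 200 genes changed. With a true log2 change of 1, the share of changed genes recovered was 95.5% for knockdown in ESC, 91.0% for knockdown in NPC and 70.1% for the difference of the effects; with a true change of 0.5 it was 64.2%, 56.7% and 5.97%. False calls numbered 6 of 179, 7 of 172 and 9 of 124. For the contrasts between NPC and ESC, 91.0% (control) and 92.5% (knockdown) were recovered at a change of 1, with 9 of 167 and 15 of 176 false calls. A list shifted by 0.4 was called in every contrast with 0 other lists called. The simulated genes varied independently, so this does not show how often lists of correlated genes are called falsely. Each simulated gene also had the same spread in all 4 groups. So the shares recovered and the false calls are not shown for genes whose spread differs between ESC and NPC.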

Results

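The series measured RNA in mouse embryonic stem cells of a feeder-independent line and in neural progenitor cells derived from such cells. Control and Jarid1b knockdown cells had 3 arrays each in both states. Jarid1b, now Kdm5b, encodes a demethylase that removes methyl groups from lysine 4 of histone H3. Arrays within a group correlated at 0.992 to 0.997 across genes, and ESC with NPC arrays at 0.920 to 0.945. No array pair of a group shared more than 0.311% identical values, so each array was counted separately. The main axis of variation held 84.2% of the variance and separated ESC from NPC. On it the knockdown NPC arrays lay at 52.4 to 58.8 and the control NPC arrays at 61.3 to 67.8, with ESC arrays at -63.1 to -55.5.

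Kdm5b (Entrez gene 75605) was lower in every knockdown array than in every control array of the same state. In ESC its level was 12.41 ± 0.14 (SD, n = 3) in control and 10.68 ± 0.20 (SD, n = 3) in knockdown cells. This was a change of -1.73 ± 0.11 (SE), or 3.31-fold lower (adjusted p = 1.82e-05). In NPC the levels were 11.23 ± 0.078 (SD, n = 3) and 10.47 ± 0.081 (SD, n = 3), a change of -0.76 ± 0.11 (SE), or 1.70-fold lower (adjusted p = 0.00524). The effects differed by 0.96 ± 0.16 (SE, adjusted p = 0.0172). That call was lost without control ESC replicate 3 (adjusted p = 0.0591) or knockdown NPC replicate 2 (adjusted p = 0.0512). From control ESC to control NPC, Kdm5b changed by -1.18 ± 0.11 (SE). The related demethylase genes were not called in either knockdown contrast. Kdm5a changed by -0.12 ± 0.11 in ESC and 0.087 ± 0.11 in NPC, Kdm5c by -0.22 ± 0.085 and -0.021 ± 0.085, and Kdm5d by 0.27 ± 0.11 and 0.048 ± 0.11 (SE).

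**Figure D1:**
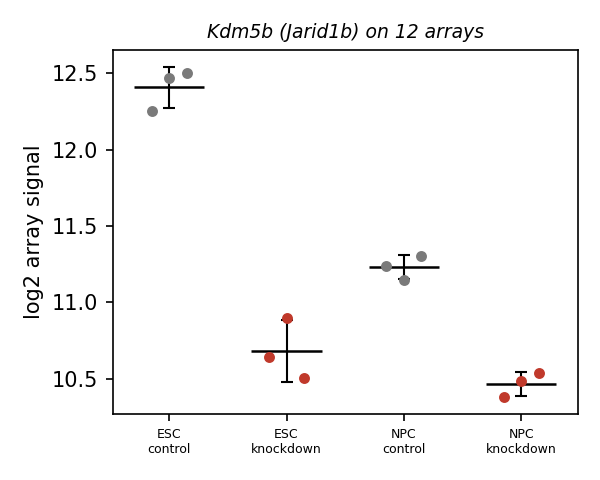
Log2 array signal of Kdm5b (vertical axis) in the 4 groups (horizontal axis), with points for arrays (gray control, red knockdown), lines for means and bars for the SD of 3 arrays. Means were 12.41 and 10.68 in control and knockdown ESC and 11.23 and 10.47 in control and knockdown NPC.

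More genes fell than rose in knockdown ESC, Lef1 and other formative and primed genes among them. Gbp2, an interferon-inducible GTPase, changed by -2.56 ± 0.46 (SE). Lef1, a transcription factor of the Wnt pathway, changed by -2.30 ± 0.32 (SE, 4.94-fold lower). Thbs1, which encodes the matrix protein thrombospondin, changed by -1.95 ± 0.42, and Tagln, an actin-binding protein of smooth muscle, by -1.89 ± 0.40 (SE). Arl14epl rose by 2.04 ± 0.21, the citrate transporter gene Slc13a5 by 1.95 ± 0.29 and Crtac1, a matrix protein gene, by 1.68 ± 0.24 (SE). These values compare 3 arrays with 3, without overlap between the groups, which the rule for naming genes required.

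Other large rises in knockdown ESC were those of Calb2 (calretinin, a calcium-binding protein, 1.57 ± 0.27), Pmel (a melanosome protein, 1.40 ± 0.20) and Slfn9 (1.29 ± 0.22). Glod5 (1.29 ± 0.21), the protease gene Klk1 (1.28 ± 0.24), the convertase inhibitor gene Pcsk1n (1.28 ± 0.17) and the desaturase gene Scd1 (1.22 ± 0.17) rose too. Other large falls were those of the semaphorin gene Sema6a (-2.07 ± 0.21), Fndc3c1 (-1.91 ± 0.26) and the carbonic anhydrase genes Car3 (-1.85 ± 0.19) and Car2 (-1.84 ± 0.22). The potassium channel gene Kcnj3 (-1.83 ± 0.25) and Efhd1 (-1.80 ± 0.16, all SE) fell as well. Klk1 lay at 4.77 in control ESC, below the lower quartiles of the arrays (5.84 to 6.11), so the size of its rise is rough. Single arrays ended 4 of these calls. Klk1 lost it without knockdown replicate 3 (adjusted p = 0.0573), and Gbp2 without control replicate 3 (0.0591). Thbs1 and Tagln lost it without control replicate 3 (0.0810 and 0.0963), knockdown replicate 2 (0.0748 and 0.0698) or knockdown replicate 3 (0.0908 and 0.0888).

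Formative and primed genes mark the step from naive pluripotency towards lineage entry. In knockdown ESC 0 rose and 7 fell of 12 (0 and 10 adjusted over the list alone). Besides Lef1 these included the DNA methyltransferase gene Dnmt3b (-1.19 ± 0.17), Sall2 (-1.21 ± 0.18) and the tight junction gene Cldn6 (-0.96 ± 0.16, SE). As a list they were lower than other genes (camera adjusted p = 6.69e-11, and adjusted p = 0.147 with an estimated correlation). Of the pluripotency genes 1 rose and 2 fell of 34 (1 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.961). They were Tcl1 (0.75 ± 0.15) and the signalling genes Nodal (-0.79 ± 0.15) and Lefty1 (-0.95 ± 0.25, SE).

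Neuronal genes were lower in knockdown ESC (camera adjusted p = 0.0280, and adjusted p = 0.655 with an estimated correlation), where 0 rose and 7 fell of 40 (2 and 10 adjusted over the list alone). They included the neurofilament gene Nefl (-1.24 ± 0.20), the neurogenic factor Neurod1 (-1.05 ± 0.16), Crmp1 (-0.94 ± 0.16) and the microtubule gene Map2 (-0.70 ± 0.13, SE). The call was lost without control replicate 1 (adjusted p = 0.0564), control replicate 2 (0.0762) or knockdown replicate 3 (0.0755). Immediate early and heat shock genes were lower (camera adjusted p = 0.00354, and adjusted p = 0.655 with an estimated correlation), and 0 rose and 3 fell of 14 (1 and 7 adjusted over the list alone). They were the transcription factors Jun (-0.94 ± 0.21) and Fosb (-1.57 ± 0.39) and the chaperone gene Dnajb1 (-0.43 ± 0.11, SE).

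In the p53 response list 0 rose and 2 fell of 14 (0 and 2 adjusted over the list alone), namely the desmosome gene Perp (-1.22 ± 0.18) and the growth inhibitor Btg2 (-0.69 ± 0.15, SE). The list was lower (camera adjusted p = 0.00354, and adjusted p = 0.655 with an estimated correlation). Of the imprinted genes 0 rose and 3 fell of 20 (1 and 6 adjusted over the list alone), namely Peg10 (-0.79 ± 0.11), Dlk1 (-0.69 ± 0.13) and Sgce (-0.70 ± 0.14, SE). This list was lower too (camera adjusted p = 0.00785, and adjusted p = 0.655 with an estimated correlation). Of the cell cycle genes 0 rose and 1 fell of 24 (0 and 1 adjusted over the list alone), which was Cdc20, an activator of the anaphase complex (-0.40 ± 0.088, SE, camera adjusted p = 0.0280, and adjusted p = 0.655 with an estimated correlation). The cell cycle call was lost without control replicate 2 (adjusted p = 0.0619), control replicate 3 (0.0552) or knockdown replicate 2 (0.0551). The filter on low values ended the neuronal and cell cycle calls (both 0.104) and the imprinted call (0.0522).

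Lists not called in ESC had camera adjusted p from 0.0734 to 0.961. Of the germ cell genes 4 rose and 0 fell of 44 (7 and 1 adjusted over the list alone), namely Hormad2 (0.79 ± 0.10), Stag3 (0.82 ± 0.13), Rpl10l (1.02 ± 0.22) and Mov10l1 (0.57 ± 0.15, SE, list adjusted p = 0.215). Of the neural progenitor genes 2 rose and 5 fell of 34 (2 and 8 adjusted over the list alone) (list adjusted p = 0.143). The cadherin gene Cdh2 (-0.99 ± 0.11) and the eye and brain factor Pax6 (-0.91 ± 0.20) fell, and the adhesion gene Ncam1 (0.76 ± 0.13, SE) rose. Of the mesoderm genes 1 rose and 3 fell of 21 (1 and 6 adjusted over the list alone), with the somite factor Tcf15 at -0.59 ± 0.088 (SE, list adjusted p = 0.0734). This list became called without control replicate 2 (adjusted p = 0.00782) or knockdown replicate 2 (0.0364), from an adjusted p of 0.655 with an estimated correlation and all arrays. Of the trophoblast genes 0 rose and 2 fell of 13 (0 and 4 adjusted over the list alone), the keratin gene Krt18 (-1.70 ± 0.39) and Cdx2 (-0.69 ± 0.16, SE, list adjusted p = 0.223). Without control replicate 2 that list was called (0.0330), while with an estimated correlation and all arrays its adjusted p was 0.893.

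Of the endoderm genes 0 rose and 1 fell of 20 (0 and 1 adjusted over the list alone), which was Dab2 (-0.99 ± 0.20, SE, list adjusted p = 0.894). The fibroblast and mesenchyme list had 0 higher and 1 lower of 16, and 2 and 1 adjusted over the list alone, with Tagln the lower one (list adjusted p = 0.625). The glial list had 0 higher and 0 lower of 12, and 1 and 0 adjusted over the list alone (list adjusted p = 0.319). The blood and immune list had 1 higher and 0 lower of 10, and 1 and 0 adjusted over the list alone, with the endothelial adhesion gene Pecam1 at 0.86 ± 0.18 (SE, list adjusted p = 0.259). Median and mean differed in sign for the pluripotency (0.0070 and -0.024), endoderm (0.049 and -0.029), fibroblast and mesenchyme (0.046 and -0.078) and cell cycle inhibitor lists (0.095 and -0.022). For the H3K4 methylation enzymes (0.0017 and 0.032) the test pointed lower.

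Among chromatin regulators in ESC, the H3K4 methylation enzymes had 0 higher and 1 lower of 17, and 0 and 1 adjusted over the list alone, which was the demethylase gene Kdm1b (-0.47 ± 0.10, SE, list adjusted p = 0.801). Kdm5b, the targeted gene, was left out of that list. The Polycomb list had 0 higher and 1 lower of 17, and 0 and 1 adjusted over the list alone, with Kdm2b at -0.73 ± 0.15 (SE, list adjusted p = 0.599). The DNA methylation list had 0 higher and 1 lower of 9, and 1 and 1 adjusted over the list alone, with Dnmt3b the lower one (list adjusted p = 0.599). Among apoptosis genes, 0 higher and 1 lower of 13, and 0 and 1 adjusted over the list alone, the death gene Bcl2l11 changed by -0.54 ± 0.092 (SE, list adjusted p = 0.0843). Cell cycle inhibitors had 0 higher and 1 lower of 13, and 1 and 2 adjusted over the list alone, with Btg2 the lower one (list adjusted p = 0.762).

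Interferon response genes had 1 higher and 1 lower of 17, and 1 and 2 adjusted over the list alone, with the signal transducer Stat2 at 0.73 ± 0.15 and Oasl2 at -0.94 ± 0.19 (SE, list adjusted p = 0.762). Glycolysis and hypoxia genes had 1 higher and 0 lower of 13, and 1 and 0 adjusted over the list alone, with the growth factor gene Vegfa at 0.71 ± 0.14 (SE, list adjusted p = 0.519). Retinoic acid response genes had 1 higher and 0 lower of 10, and 2 and 0 adjusted over the list alone, with the binding protein gene Crabp1 at 0.74 ± 0.16 (SE, list adjusted p = 0.379). No member was called, over all genes or adjusted over the list alone, in 5 further lists. These were Hox (38 measured, list adjusted p = 0.808), 2-cell-like (5 measured, 0.379), unfolded protein and amino acid response (12 measured, 0.625), cholesterol synthesis (9 measured, 0.599) and Y-linked and Xist (4 measured, 0.961).

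Over all genes, 979 of 18784 passed limma's test in ESC, 346 higher and 633 lower, of which 25 and 75 changed at least 2-fold. An unadjusted p under 0.05 was found for 3603. Groups did not overlap for 24.2% of genes, against 10% by chance. The count was 1536, 621 and 193 without control replicates 1, 2 and 3. It was 633, 472 and 283 without knockdown replicates 1, 2 and 3. With array weights it was 2887, and from the 6 ESC arrays alone 500. Of the 6 lists called, all lower, 0 were called with an estimated correlation and 1, formative and primed, with fry.

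**Figure D2:**
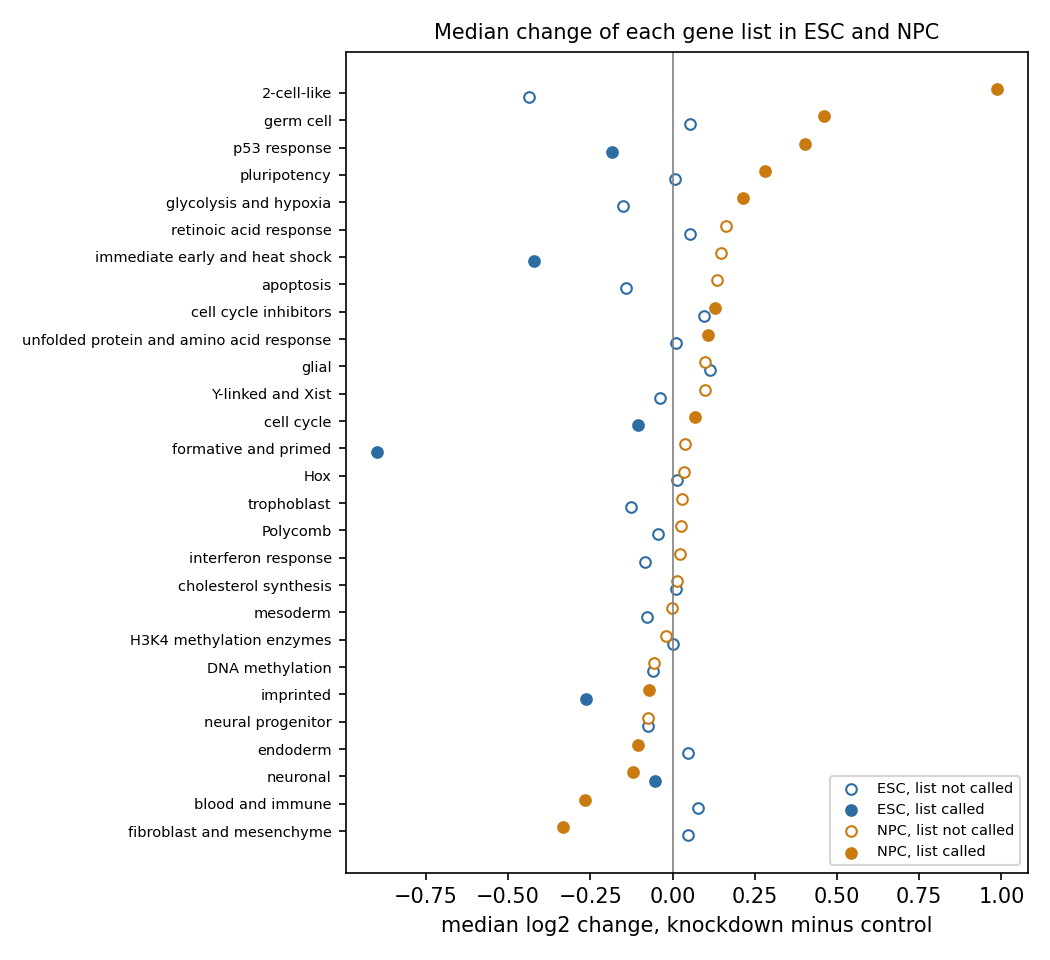
Median log2 change of the measured genes of each of the 28 lists (vertical axis), knockdown minus control (horizontal axis), in ESC (blue) and NPC (orange), with filled points for lists called by camera at the preset correlation. The formative and primed genes lie at -0.90 in ESC, and the germ cell and pluripotency genes at 0.46 and 0.28 in NPC.

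In knockdown NPC germ cell genes such as Mael rose, as did 9 of 34 pluripotency genes, while Emcn and Cdh5 had the largest falls. Mael, which acts in transposon silencing in germ cells, rose by 2.57 ± 0.21 (SE, 5.93-fold). Dazl, a germ cell RNA-binding protein, rose by 1.98 ± 0.22, and Sycp3, part of the synaptonemal complex of meiosis, by 2.02 ± 0.37 (SE). Dppa5a and Dppa2, expressed in pluripotent cells, rose by 2.43 ± 0.37 and 2.26 ± 0.28, and Dnmt3l, a cofactor of DNA methylation, by 2.21 ± 0.23 (SE). Emcn and Cdh5, which encode endomucin and the cadherin of endothelial junctions, changed by -2.58 ± 0.37 and -1.98 ± 0.29 (SE). All compare 3 arrays with 3, without overlap between the groups, which the rule for naming genes required. The SE pools the spread of all 4 groups. For Emcn the SD was 0.92 and 0.63 in control and knockdown NPC but 0.12 and 0.068 in ESC. For Cdh5 it was 0.74 and 0.45 but 0.13 and 0.081, and for Dppa5a 0.72 and 0.85 but 0.031 and 0.024. So the SEs of these genes are smaller than the NPC spread alone would give, and their p-values rest on them.

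Other large rises were those of the zinc finger genes Zfp980 (2.93 ± 0.43) and Zfp979 (1.98 ± 0.12), the meiotic entry gene Stra8 (2.29 ± 0.33) and the germ cell transcription factor Sohlh2 (2.23 ± 0.26). Other large falls were those of Rasgrp3 (-1.78 ± 0.26), Cd93 (-1.73 ± 0.20), the matrix gene Sparcl1 (-1.66 ± 0.24) and the endothelial receptor gene Adgrl4 (-1.46 ± 0.25). Asb4 (-1.38 ± 0.26), the GTPase gene Rhoj (-1.37 ± 0.22), the semaphorin receptor gene Plxnd1 (-1.18 ± 0.21) and the growth factor gene Bmp5 (-0.99 ± 0.15, all SE) fell as well. In control NPC Zfp979 (3.82), Dppa2 (4.39), Zfp980 (4.77 ± 1.28, SD) and Sycp3 (4.85) lay below the lower quartiles of the arrays (5.84 to 6.11). So did Adgrl4 (4.85), Rasgrp3 (4.98) and Cd93 (5.36) in knockdown NPC. The sizes of these changes, and their order, are rough. Single arrays ended 4 of these calls. Sycp3 lost it without control replicate 1 (adjusted p = 0.0553), control replicate 3 (0.0608) or knockdown replicate 1 (0.0503). Adgrl4 lost it without knockdown replicate 2 (0.0576). Asb4 lost it without control replicate 2 (0.0686), knockdown replicate 2 (0.0860) or knockdown replicate 3 (0.0821). Plxnd1 lost it without control replicate 3 (0.0509) or knockdown replicate 2 (0.0667).

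Of the germ cell genes 14 rose and 0 fell of 44 (23 and 0 adjusted over the list alone). Besides Mael, those with the smallest p were the meiotic cohesin gene Stag3 (1.60 ± 0.13), the helicase gene Mov10l1 of the piRNA pathway (1.43 ± 0.15) and the germ cell helicase gene Ddx4 (1.59 ± 0.17, SE). The list was higher than other genes (camera adjusted p = 8.47e-27, and adjusted p = 0.0141 with an estimated correlation). Of the pluripotency genes 9 rose and 0 fell of 34 (15 and 0 adjusted over the list alone), including Dnmt3l, Dppa2, the chromatin gene Utf1 (1.44 ± 0.21) and the transcription factor Klf2 (0.98 ± 0.11, SE). That list was higher too (camera adjusted p = 2.69e-15, and adjusted p = 0.0867 with an estimated correlation). The core factors Pou5f1 (0.89 ± 0.25, adjusted p = 0.144) and Nanog (2.03 ± 0.52, SE, adjusted p = 0.100), chosen after their values were seen, did not pass the test. The NPC knockdown arrays correlated with the ESC arrays at 0.938 on average, and the NPC control arrays at 0.926.

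**Figure D3:**
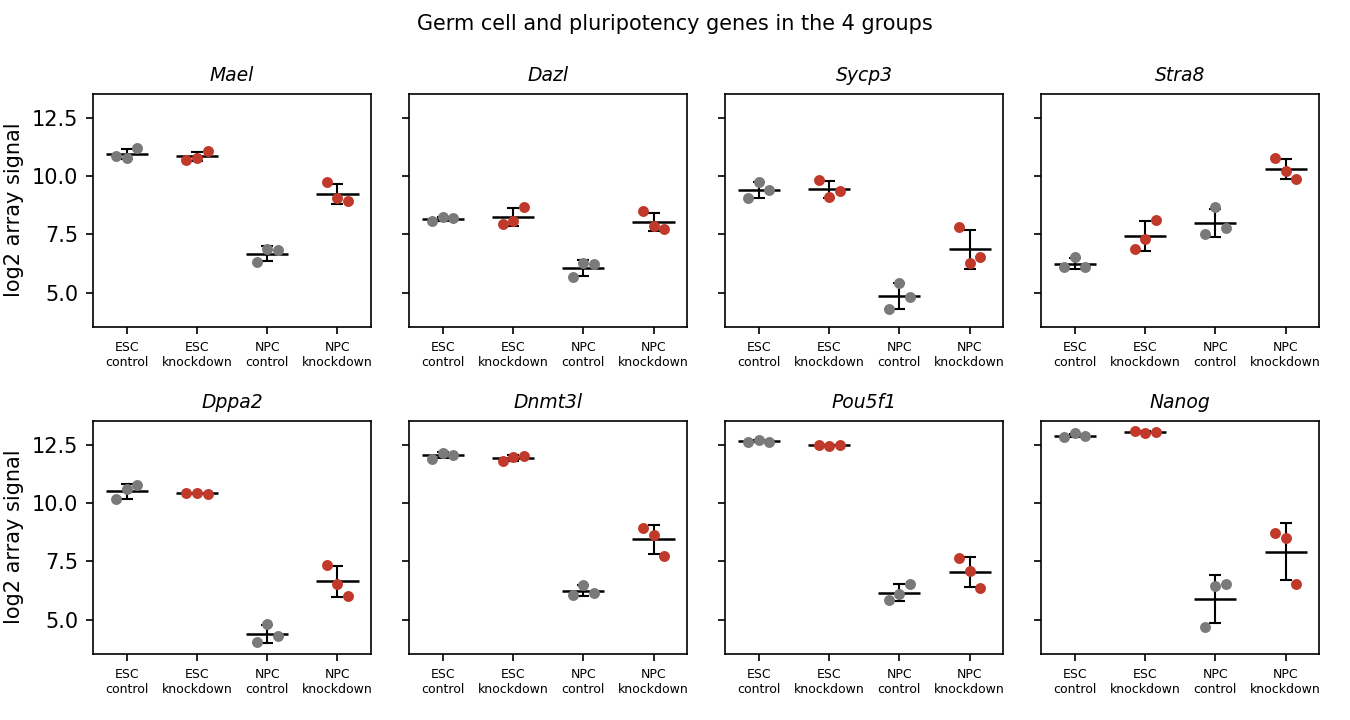
Log2 array signal (vertical axes) of 8 genes in the 4 groups (horizontal axes), with points for arrays (gray control, red knockdown), lines for means and bars for the SD of 3 arrays. Mael, Dazl, Sycp3, Stra8, Dppa2 and Dnmt3l rose in knockdown NPC, by 1.98 to 2.57 on the log2 scale, while Pou5f1 and Nanog at 0.89 and 2.03 did not pass the test.

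In the p53 response list 1 rose and 0 fell of 14 (11 and 0 adjusted over the list alone), with Trp53inp1 at 0.69 ± 0.11 (SE, camera adjusted p = 1.17e-13, and adjusted p = 0.0867 with an estimated correlation). Of the glycolysis and hypoxia genes 1 rose and 0 fell of 13 (3 and 0 adjusted over the list alone), with the phosphofructokinase gene Pfkp at 0.69 ± 0.14 (SE, camera adjusted p = 2.93e-05, and adjusted p = 0.166 with an estimated correlation). The 2-cell-like list had 0 higher and 0 lower of 5, and 3 and 0 adjusted over the list alone (camera adjusted p = 0.000494, and adjusted p = 0.166 with an estimated correlation), with the smallest p for Usp17la (1.97 ± 0.45, SE). Cell cycle inhibitors had 0 higher and 0 lower of 13, and 3 and 0 adjusted over the list alone (camera adjusted p = 0.00563, and adjusted p = 0.155 with an estimated correlation), with the smallest p for Btg2 (0.55 ± 0.15, SE). This call was lost without knockdown replicate 1 (0.0890).

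Cell cycle genes had 0 higher and 0 lower of 24, and 0 and 0 adjusted over the list alone (camera adjusted p = 0.0126, and adjusted p = 0.385 with an estimated correlation), with the smallest p for the cyclin gene Ccne1 (0.23 ± 0.082, SE). The call was lost without control replicate 2 (0.228) or knockdown replicate 1 (0.0656). Unfolded protein and amino acid response genes had 0 higher and 0 lower of 12, and 2 and 0 adjusted over the list alone (camera adjusted p = 0.0156, and adjusted p = 0.515 with an estimated correlation). Without control replicate 2 (0.303) or knockdown replicate 1 (0.285) they were not called.

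Of the lists of other cell types, 4 were lower in the same NPC arrays, while the glial (median 0.098, adjusted p = 0.288), trophoblast (0.030, 0.484) and mesoderm lists (-0.00067, 0.605) were not called. Of the blood and immune genes 0 rose and 3 fell of 10 (0 and 5 adjusted over the list alone), namely Cdh5 and the embryonic globin genes Hbb-y (-0.89 ± 0.15) and Hba-x (-0.63 ± 0.13, SE, camera adjusted p = 2.14e-05, and adjusted p = 0.118 with an estimated correlation). Of the fibroblast and mesenchyme genes 0 rose and 1 fell of 16 (0 and 4 adjusted over the list alone), which was the matrix gene Postn (-0.81 ± 0.17, SE, camera adjusted p = 6.28e-08, and adjusted p = 0.118 with an estimated correlation). The endoderm list had 0 higher and 0 lower of 20, and 0 and 4 adjusted over the list alone (camera adjusted p = 0.00172, and adjusted p = 0.166 with an estimated correlation), with the smallest p for the matrix gene Sparc (-0.62 ± 0.14, SE). The neuronal list had 0 higher and 0 lower of 40, and 0 and 1 adjusted over the list alone (camera adjusted p = 0.000351, and adjusted p = 0.118 with an estimated correlation), with the smallest p for Gad2, an enzyme of GABA synthesis (-0.47 ± 0.11, SE).

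Of the imprinted genes 0 rose and 1 fell of 20 (1 and 2 adjusted over the list alone) in NPC, which was Dlk1 (-0.71 ± 0.13, SE, camera adjusted p = 0.00563, and adjusted p = 0.209 with an estimated correlation). That list call was lost without control replicate 3 (0.233) or knockdown replicate 3 (0.0548). Of the neural progenitor genes 0 rose and 1 fell of 34 (1 and 2 adjusted over the list alone), which was the growth factor gene Ptn (-0.60 ± 0.13, SE). They were not called as a list (adjusted p = 0.0712) except without control replicate 3 (0.0455). Immediate early and heat shock genes became called without control replicate 3 (0.000750) or knockdown replicate 2 (0.00162), and apoptosis genes without the same arrays (0.0139 and 0.0291). Cholesterol synthesis genes did without control replicate 3 (0.0333) and Hox genes without knockdown replicate 2 (0.00786). With an estimated correlation and all arrays none was called. The adjusted p was 0.390 (neural progenitor), 0.710 (immediate early and heat shock), 0.284 (apoptosis), 0.856 (cholesterol synthesis) and 0.720 (Hox). Median and mean differed in sign for the interferon response (0.021 and -0.011) and DNA methylation lists (-0.056 and 0.23), which were not called.

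In all, 194 of 18784 genes passed limma's test in NPC, 154 higher and 40 lower, of which 60 and 9 changed at least 2-fold. An unadjusted p under 0.05 was found for 1789, and groups did not overlap for 14.2% of genes, against 10% by chance. The count was 98 without control replicate 2, 83 without knockdown replicate 1 and 91 without knockdown replicate 2. Without control replicate 1 it was 220, with 112 higher and 108 lower. From the 6 NPC arrays alone it was 29. Of the 13 lists called, 8 higher and 5 lower, 1 (germ cell) was called with an estimated correlation and 4 with fry. The 15 others had camera adjusted p from 0.0581 to 0.737.

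**Figure D4:**
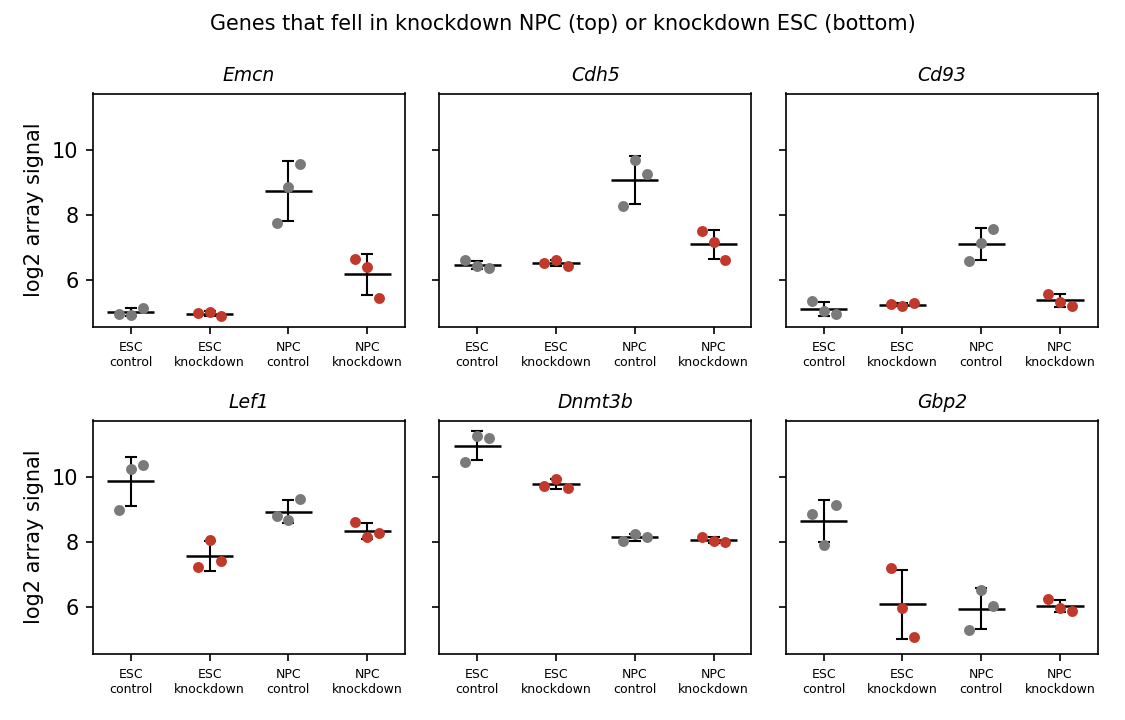
Log2 array signal (vertical axes) of 6 genes in the 4 groups (horizontal axes), with points for arrays (gray control, red knockdown), lines for means and bars for the SD of 3 arrays. Emcn, Cdh5 and Cd93 changed by -2.58, -1.98 and -1.73 in knockdown NPC, and Lef1, Dnmt3b and Gbp2 by -2.30, -1.19 and -2.56 in knockdown ESC.

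The effect of knockdown differed between the states for Mael and Car2, among other single genes. Kdm5b itself changed by -1.73 in ESC and -0.76 in NPC, so the depth of knockdown differed too. The contrast does not separate that from a difference between the states. As the NPC effect minus the ESC effect, Zfp980 had 3.10 ± 0.61, Mael 2.66 ± 0.29, Car2 2.41 ± 0.32 and Dppa5a 2.38 ± 0.52 (SE). Dppa2 had 2.34 ± 0.39, Dnmt3l 2.33 ± 0.33, Zfp979 2.11 ± 0.16 and the meiosis gene Meioc 2.08 ± 0.32 (SE). On the other side, Emcn had -2.53 ± 0.52, Sparcl1 -2.08 ± 0.33, Cdh5 -2.05 ± 0.41 and Rasgrp3 -1.93 ± 0.37 (SE). Crtac1 had -1.88 ± 0.34, Cd93 -1.87 ± 0.28, Rhoj -1.70 ± 0.31 and Pecam1 -1.55 ± 0.26 (SE). In control ESC Emcn (4.99), Cd93 (5.10), Rasgrp3 (5.15), Sparcl1 (5.52) and Rhoj (5.58) lay below the lower quartiles of the arrays (5.84 to 6.11). So near the floor a fall in ESC can hardly be seen. Dppa5a (13.70) lay near the maxima of the control ESC arrays (14.17 to 14.26), where a rise can hardly be seen. In control NPC Zfp979 (3.82), Dppa2 (4.39) and Zfp980 (4.77) lay below those quartiles, so the sizes of these differences are rough. Counting Kdm5b, 11 of these 17 genes lost the call without some array, while Mael, Car2, Dnmt3l, Zfp979, Meioc and Cd93 kept it throughout. With the replicate block Dppa5a (adjusted p = 0.0556), Emcn (0.0585) and Cdh5 (0.0510) lost it, and with the intensity trend and robust prior Zfp980 (0.0521) and Dppa5a (0.0704) did. The number lost (adjusted p) without control ESC replicates 2 and 3 was 5 (0.0567 to 0.0817) and 11 (0.0584 to 0.117). Without knockdown ESC replicates 1, 2 and 3 it was 5 (0.0509 to 0.0780), 6 (0.0599 to 0.0962) and 9 (0.0608 to 0.107). Without control NPC replicates 1, 2 and 3 it was 1 (0.0626), 5 (0.0515 to 0.0814) and 3 (0.0538 to 0.0566). Without knockdown NPC replicates 1, 2 and 3 it was 5 (0.0539 to 0.106), 11 (0.0505 to 0.109) and 3 (0.0558 to 0.0644).

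Several lists had a more positive effect in NPC. The p53 response list had 5 higher and 0 lower of 14, and 12 and 0 adjusted over the list alone, with Perp at 1.90 ± 0.25 and Btg2 at 1.24 ± 0.21 (SE, camera adjusted p = 8.73e-11, and adjusted p = 0.144 with an estimated correlation). The formative and primed list had 3 higher and 0 lower of 12, and 11 and 0 adjusted over the list alone, with Cldn6 at 1.15 ± 0.23 and Dnmt3b at 1.12 ± 0.24 (SE, camera adjusted p = 4.26e-09, and adjusted p = 0.144 with an estimated correlation). The germ cell list had 8 higher and 0 lower of 44, and 15 and 1 adjusted over the list alone, with Ddx4 at 1.68 ± 0.25 (SE, camera adjusted p = 1.55e-08, and adjusted p = 0.144 with an estimated correlation). The pluripotency list had 7 higher and 0 lower of 34, and 13 and 0 adjusted over the list alone, with Nodal at 1.53 ± 0.21 and Klf2 at 0.99 ± 0.15 (SE, camera adjusted p = 7.59e-07, and adjusted p = 0.276 with an estimated correlation).

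Further lists had a more positive effect in NPC without a member called over all genes. Immediate early and heat shock genes had 0 higher and 0 lower of 14, and 4 and 0 adjusted over the list alone (smallest p for Jun, 1.07 ± 0.30, SE, camera adjusted p = 0.000164, and adjusted p = 0.309 with an estimated correlation). Cell cycle genes had 0 higher and 0 lower of 24, and 1 and 0 adjusted over the list alone (Ccne1 0.48 ± 0.12, SE, camera adjusted p = 0.000495, and adjusted p = 0.294 with an estimated correlation). Glycolysis and hypoxia genes had 0 higher and 0 lower of 13, and 4 and 1 adjusted over the list alone (Egln3 0.88 ± 0.24, SE, camera adjusted p = 0.00159, and adjusted p = 0.320 with an estimated correlation). 2-cell-like genes had 0 higher and 0 lower of 5, and 3 and 0 adjusted over the list alone (Usp17la 2.72 ± 0.64, SE, camera adjusted p = 0.00287, and adjusted p = 0.294 with an estimated correlation). Apoptosis genes had 0 higher and 0 lower of 13, and 5 and 0 adjusted over the list alone (Bcl2l11 0.53 ± 0.13, SE, camera adjusted p = 0.00502, and adjusted p = 0.222 with an estimated correlation).

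More negative effects in NPC were found for 3 lists. The blood and immune list had 0 higher and 3 lower of 10, and 0 and 4 adjusted over the list alone, with Hbb-y at -1.15 ± 0.21 (SE, camera adjusted p = 0.000164, and adjusted p = 0.222 with an estimated correlation). The fibroblast and mesenchyme list had 0 higher and 0 lower of 16, and 0 and 4 adjusted over the list alone (Col6a1 -0.47 ± 0.13, SE, camera adjusted p = 0.000164, and adjusted p = 0.294 with an estimated correlation). The endoderm list had 0 higher and 0 lower of 20, and 0 and 0 adjusted over the list alone (Col4a1 -0.54 ± 0.16, SE, camera adjusted p = 0.0484, and adjusted p = 0.367 with an estimated correlation). The endoderm call was lost with the replicate block (adjusted p = 0.0816) and without control ESC replicate 2 (adjusted p = 0.116), knockdown ESC replicate 2 (0.126), control NPC replicates 2 and 3 (0.0847 and 0.0965) or knockdown NPC replicates 2 and 3 (0.0550 and 0.0950). Trophoblast genes (adjusted p = 0.0887) became called without control ESC replicates 2 and 3 (0.00834 and 0.0324), knockdown ESC replicate 1 (0.0361) or knockdown NPC replicate 3 (0.00977). DNA methylation genes (0.268) did without control ESC replicate 1 (0.0339). With an estimated correlation and all arrays the adjusted p was 0.779 for trophoblast and 0.799 for DNA methylation genes. Among lists not called, median and mean differed in sign for the neuronal list (-0.024 and 0.030) and the H3K4 methylation enzymes (0.019 and -0.11). For the retinoic acid response (0.051 and 0.097) the test pointed lower.

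Over all genes the effects differed for 267 of 18784, 221 higher and 46 lower in NPC. This was 82.8% higher, against 71.1% after median centring and 71.4% after quantile normalization. With the replicate block the count was 152, and with array weights 955. The count was 546, 151 and 40 without control ESC replicates 1, 2 and 3, and 154, 75 and 45 without knockdown ESC replicates 1, 2 and 3. It was 97 without control NPC replicate 2, and 71, 35 and 176 without knockdown NPC replicates 1, 2 and 3. Of the 12 lists called, 0 were called with an estimated correlation and 7 with fry.

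Stag3, Mov10l1, Cox7a1, Got1l1 and Morc1, a silencer of transposons in the male germ line, rose in both states. Kdm5b, Dlk1, the stress response gene Sesn3 and Igsf9 were among those that fell in both. Cox7a1, Got1l1, Sesn3 and Igsf9 were chosen after their values were seen. In all 17 genes were called in both, 5 higher in both (2.84 for independent lists) and 8 lower in both (1.35), the targeted Kdm5b included. The other 4 fell in ESC and rose in NPC (5.19 for independent lists), and 0 went the reverse way (0.737). Across genes the knockdown effects, which share no arrays, correlated at 0.0458 (Spearman -0.0111), with genes not being independent replicates. The correlation was -0.0530 without control NPC replicate 3 and 0.109 without control NPC replicate 2.

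From control ESC to control NPC, pluripotency genes fell and neural genes rose. Nanog changed by -7.00 ± 0.52, Pou5f1 by -6.50 ± 0.25, Tdgf1 by -6.91 ± 0.19 and Fbxo15 by -6.30 ± 0.40 (SE). Zfp980 changed by -7.15 ± 0.43, Zfp979 by -6.28 ± 0.12, Dppa2 by -6.13 ± 0.28 and Dnmt3l by -5.81 ± 0.23 (SE). The nicotinic receptor gene Chrna3 rose by 6.13 ± 0.11, the radial glia gene Fabp7 by 6.02 ± 0.25, Tfap2b by 5.65 ± 0.14 and the ephrin receptor gene Epha3 by 5.60 ± 0.19 (SE). The neuroblast gene Dcx rose by 5.59 ± 0.11, Dach1 by 5.37 ± 0.18, the retinoic acid receptor gene Rarb by 5.35 ± 0.20 and the spinal progenitor gene Dbx1 by 5.08 ± 0.18 (SE, n = 3 arrays a group). In control NPC Nanog (5.90 ± 1.03, SD), Fbxo15 (5.27), Zfp980 (4.77), Dppa2 (4.39) and Zfp979 (3.82) lay near or below the lower quartiles of the arrays. So did Chrna3 (5.79), Tfap2b (5.68), Dach1 (5.63), Epha3 (5.38) and Dcx (5.13) in control ESC, so the sizes of these changes are rough.

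In knockdown cells the same contrast gave rises of Fabp7 (6.62 ± 0.25), Chrna3 (5.72 ± 0.11), Epha3 (5.72 ± 0.19) and Tfap2b (5.55 ± 0.14, SE). Rarb (5.46 ± 0.20), Dach1 (5.41 ± 0.18), the integrin gene Itgb8 (5.26 ± 0.14) and Cyp26a1, which degrades retinoic acid (5.16 ± 0.28, SE), rose as well. Large falls were those of Tdgf1 (-6.07 ± 0.19), Tcl1 (-5.53 ± 0.15), Pou5f1 (-5.44 ± 0.25) and Zfp42 (-5.21 ± 0.16, SE). Nanog (-5.13 ± 0.52), Lrrc2 (-5.11 ± 0.19), Esrrb (-5.05 ± 0.11) and Morc1 (-4.87 ± 0.13, SE) followed. Tcl1 (5.76) and Zfp42 (5.53) in knockdown NPC lay near or below the lower quartiles of the arrays. So did Epha3 (5.42), Dach1 (5.50), Tfap2b (5.55), Fabp7 (5.86), Cyp26a1 (5.93), Itgb8 (6.02) and Chrna3 (6.11) in knockdown ESC, so these sizes and their order are rough. Control cells had 9122 genes past limma's threshold, 4406 higher and 4716 lower in NPC, and knockdown cells 9164, 4469 and 4695. In both, 3684 rose and 3618 fell. At least 2-fold changes numbered 2931 and 2754.

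All 34 pluripotency genes fell in control and in knockdown cells, also adjusted over the list alone (camera adjusted p = 1.74e-24 and 9.80e-23, 0.0225 and 0.0279 with an estimated correlation). Germ cell genes fell in 35 of 44 cases in control cells (36 adjusted over the list alone, camera adjusted p = 7.43e-10, and adjusted p = 0.0669 with an estimated correlation). In knockdown cells 24 of 44 fell (24 adjusted over the list alone, camera adjusted p = 2.70e-05, and adjusted p = 0.200 with an estimated correlation). Neural progenitor genes rose in 31 and 29 of 34 cases in control and knockdown cells and fell in 2 and 0 (31 and 30, and 2 and 0, adjusted over the list alone). Their camera adjusted p was 5.47e-15 and 7.65e-15 (0.0142 and 0.00826 with an estimated correlation), and Zic1, a patterning factor, rose by 4.74 ± 0.14 (SE) in control cells. Neuronal genes rose in 31 and 33 of 40 cases and fell in 2 and 1, also adjusted over the list alone (camera adjusted p = 5.98e-12 and 4.69e-14, 0.0142 and 0.00826 with an estimated correlation).

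Hox genes, which pattern the body axis, rose in 23 and fell in 6 of 38 cases in control cells (23 and 6 adjusted over the list alone, camera adjusted p = 1.49e-07, and adjusted p = 0.197 with an estimated correlation). In knockdown cells 24 rose and 4 fell (24 and 5 adjusted over the list alone, camera adjusted p = 1.30e-08, and adjusted p = 0.200 with an estimated correlation), and Hoxa2 rose by 5.05 ± 0.11 (SE) in control cells. Retinoic acid response genes rose in 10 of 10 cases in control cells (10 adjusted over the list alone, camera adjusted p = 1.49e-07, and adjusted p = 0.0669 with an estimated correlation). In knockdown cells 9 rose (9 adjusted over the list alone, camera adjusted p = 3.46e-07, and adjusted p = 0.0930 with an estimated correlation). Cell cycle genes fell in 19 and 18 of 24 cases and rose in 0 and 1 (20 and 18, and 1 and 1, adjusted over the list alone, camera adjusted p = 1.38e-05 and 0.00217). With the correlation estimated the calls were lost (adjusted p = 0.184 with an estimated correlation in control cells, and adjusted p = 0.335 with an estimated correlation in knockdown cells).

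Imprinted genes rose in 13 of 20 cases in each contrast and fell in 4 (control) and 6 (knockdown), also adjusted over the list alone, with Dlk1 at 2.98 ± 0.13 (SE) in control cells. Their camera adjusted p was 0.00232 in control cells (adjusted p = 0.212 with an estimated correlation) and 0.00365 in knockdown cells (adjusted p = 0.241 with an estimated correlation). Cholesterol synthesis genes rose in 8 and 7 of 9 cases, also adjusted over the list alone, with Cyp51 at 1.84 ± 0.13 (SE) in control cells. Their camera adjusted p was 0.000618 (adjusted p = 0.382 with an estimated correlation) and 0.000798 (adjusted p = 0.428 with an estimated correlation). Cell cycle inhibitors rose in 9 and 8 of 13 cases, also adjusted over the list alone, and fell in 1 and 1 (2 and 1 adjusted over the list alone), with camera adjusted p = 0.0381 (adjusted p = 0.295 with an estimated correlation) and 0.0116 (adjusted p = 0.200 with an estimated correlation). In control cells this call was lost without control NPC replicate 3 (0.0550).

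In control cells endoderm genes were called higher (9 higher and 1 lower of 20, and 9 and 1 adjusted over the list alone, camera adjusted p = 0.0334, and adjusted p = 0.371 with an estimated correlation), as were fibroblast and mesenchyme genes (11 higher and 2 lower of 16, and 11 and 2 adjusted over the list alone, camera adjusted p = 0.0154, and adjusted p = 0.448 with an estimated correlation). The p53 response list was lower in control cells (2 higher and 9 lower of 14, and 2 and 9 adjusted over the list alone, camera adjusted p = 0.0379, and adjusted p = 0.478 with an estimated correlation), a call lost without control ESC replicate 3 (0.0714). In knockdown cells the p53 list had 4 higher and 2 lower, and 5 and 2 adjusted over the list alone (camera adjusted p = 0.397). There endoderm genes had 8 higher and 2 lower (0.337) and fibroblast and mesenchyme genes 3 and 1 (0.487), also adjusted over the list alone. DNA methylation genes were lower in control cells (1 higher and 5 lower of 9, and 1 and 5 adjusted over the list alone, camera adjusted p = 0.0348, and adjusted p = 0.448 with an estimated correlation), a call lost without control ESC replicate 2 (0.0651). In knockdown cells immediate early and heat shock genes were higher (9 higher and 3 lower of 14, and 9 and 3 adjusted over the list alone, camera adjusted p = 0.0464, and adjusted p = 0.656 with an estimated correlation). This was lost without knockdown ESC replicates 2 and 3 (0.0616 and 0.0557) or knockdown NPC replicate 1 (0.112). In control cells that list had 5 higher and 5 lower of 14, and 5 and 5 adjusted over the list alone (camera adjusted p = 0.558). In knockdown cells the DNA methylation list had 1 higher and 6 lower of 9, and 1 and 6 adjusted over the list alone (camera adjusted p = 0.0831), and it became called without knockdown NPC replicate 3 (0.0405).

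With the replicate block, which takes the control arrays as paired, 2-cell-like genes (adjusted p = 0.0485) and interferon response genes (0.0490) were called as lower in control cells. Without the block their camera adjusted p was 0.0597 and 0.0555. With an estimated correlation and no block both had an adjusted p of 0.448. Without control ESC replicate 1 the 2-cell-like (0.0198) and formative and primed lists (0.0233) were called, from 0.0726 for the latter with all arrays and 0.478 with an estimated correlation. Interferon response genes were called without control ESC replicate 2 (0.0477) or control NPC replicates 1 and 2 (0.0496 and 0.0419). Of the 14 and 11 lists called in control and knockdown cells, pluripotency, neural progenitor and neuronal genes, 3 in each, were called with an estimated correlation. Among lists not called, median and mean differed in sign in control cells for glial (-0.18 and 0.14), trophoblast (0.12 and -0.69) and blood and immune genes (-0.031 and 0.049). In knockdown cells they did for glial (-0.15 and 0.11), trophoblast (0.033 and -0.26) and apoptosis genes (-0.039 and 0.12), and for glycolysis and hypoxia genes (-0.035 and -0.14) the test pointed higher.

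Genes changed by knockdown in NPC lay along this axis. Of the 154 that rose, such as Mael and Dppa2, 140 had fallen from control ESC to control NPC, against 38.7 for independent lists. From knockdown ESC to knockdown NPC 110 had fallen, against 38.5. Of the 40 that fell, such as Emcn, 38 had risen in control cells (9.38 for independent lists) and 21 in knockdown cells (9.52). Across genes the NPC effect correlated at -0.444 with the change between states in control cells (covariance -0.0798), where shared arrays alone gave -0.500 (covariance -0.00846). With the change in knockdown cells it correlated at -0.229 (covariance -0.0397), where shared arrays alone gave 0.501 (covariance 0.00848). The covariance minus the simulated one was -0.0713 and -0.0482. Shared arrays add to the overlap in control cells and work against that in knockdown cells.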

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

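The lists of endothelial genes and of SRF and YAP targets were written after the falls of Emcn, Cdh5, Ccn1, Thbs1 and Tagln had been seen and before the lists were tested, and the test of 4 other non-neural lists was chosen after its result had been seen. The values of Ccn1, a gene named beyond the rule, are not given here.

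The interaction test put 267 genes past its threshold, so that the knockdown effect differed between NPC and ESC. Kdm5b is 1 of them, with a weaker fall in NPC (-0.76) than in ESC (-1.73). A difference between the states thus cannot be told apart from a difference in the depth of knockdown. With the effect in NPC minus that in ESC on the log2 scale, the genes more positive in NPC were Zfp980 (3.10), Mael (2.66), Car2 (2.41), Dppa5a (2.38), Dppa2 (2.34), Dnmt3l (2.33), Zfp979 (2.11), Meioc (2.08), Dazl (1.91), Kcnj3 (1.89), Efhd1 (1.88), Sema6a (1.87), Fndc3c1 (1.66), Car3 (1.61) and Kdm5b itself (0.96). Those more negative in NPC were Emcn (-2.53), Sparcl1 (-2.08), Cdh5 (-2.05), Rasgrp3 (-1.93), Crtac1 (-1.88), Cd93 (-1.87), Rhoj (-1.70), Pecam1 (-1.55), Pmel (-1.30) and Bmp5 (-1.02). Of these Emcn (4.99), Cd93 (5.10), Rasgrp3 (5.15), Sparcl1 (5.52), Rhoj (5.58) and Bmp5 (5.74) lay below the lower quartiles of the arrays (5.84 to 6.11) in control ESC, where a fall can hardly be seen. Zfp979 (3.82), Dppa2 (4.39) and Zfp980 (4.77) did in control NPC, so the sizes of all these differences are rough. Dppa5a (13.70) lay near the maxima of the control ESC arrays (14.17 to 14.26), where a rise can hardly be seen. The lists past the same test had median differences of 1.53 (2-cell-like), 0.98 (formative and primed), 0.63 (p53 response), 0.49 (immediate early and heat shock), 0.44 (pluripotency), 0.35 (germ cell), 0.27 (glycolysis and hypoxia), 0.24 (apoptosis), 0.17 (cell cycle), -0.12 (endoderm), -0.31 (blood and immune) and -0.44 (fibroblast and mesenchyme). With an estimated correlation 0 of the 12 were called (adjusted p from 0.144 to 0.367), and several have no member called over all genes. Of the probe sets with no single listed gene, which were left out of the gene counts, 65 passed the threshold in ESC knockdown and 10 in NPC knockdown.

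The rise of pluripotency and germ cell genes in knockdown NPC might come from a larger share of undifferentiated cells in those cultures. Such cells would bring all their transcripts, and 77 other genes at least 8-fold higher in ESC had a median NPC effect of 0.46 (95% bootstrap interval 0.33 to 0.59). The implied share of ESC-like signal, on the linear scale, had a median of 1.60% over 24 pluripotency genes. This lay inside the 1.38% to 3.51% of 10000 matched lists, so this explanation stays open for their median. Single genes, chosen after their values were seen, differed. Dppa2 lay at 4.39 in control and 6.64 in knockdown NPC, Zfp42 at 5.40 and 5.53, and Nr0b1 at 8.59 and 8.52. In knockdown ESC they lay at 10.43, 10.74 and 12.74, so the median does not show that 1 share fits every gene. Dppa2 and Zfp42 lay near the floor in control NPC. For 20 germ cell genes the median share was 22.0%, above 0.739% to 7.58%, which argues against this explanation as the whole cause there. With control and knockdown arrays pooled in the denominator, a version computed and seen first by mistake, the medians were 1.70% and 28.6%, on the same side of their matched lists. An effect of Kdm5b itself remains a hypothesis, and effects of the shRNA beyond its target were not tested.

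The fall of Emcn, Cdh5 and Cd93 might reflect fewer endothelial cells in the knockdown NPC cultures. The 24 other endothelial markers, of which 0 were called singly, had a median change of -0.32, below the -0.071 to 0.062 of matched lists; the largest falls were Cd34 (-1.27 ± 0.30) and Kdr (-1.02 ± 0.23, SE). A loss of all non-neural cells was not decided. Of 4 other lists 2 lay below their matched lists, fibroblast and mesenchyme (-0.33) and endoderm (-0.11). The mesoderm (-0.00067) and trophoblast medians (0.030) lay inside theirs, while such a loss should lower all 4. In that order, 2 of 16, 6 of 20, 10 of 21 and 7 of 13 members had estimates above 0. So what such a loss predicts was met by 2 of the 4 lists. The medians inside were taken to decide nothing because members of those lists went both ways, a rule written after the result. Neuronal genes, which such a loss would not lower, were lower as well (median -0.12, camera adjusted p = 0.000351, and adjusted p = 0.118 with an estimated correlation). Of the 24 markers 16 had a mean above 7 in control ESC too, so the list is not specific, and lower transcription of these genes in the same cells stays open.

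The fall of Lef1, Thbs1, Tagln and the formative and primed genes in knockdown ESC may reflect fewer primed or differentiating cells, or a difference in adhesion or growth signalling at harvest. In line with the former, 147 genes at least 8-fold higher in NPC had a median ESC effect of -0.13, below the 0.027 to 0.087 of lists matched on the ESC level. In line with the latter, 20 other SRF and YAP targets had a median of -0.54, below the -0.14 to 0.070 of matched lists, with 9 of 20 called lower, Ccn2 (-1.27 ± 0.19) and Srf itself (-0.53 ± 0.079, SE) among them. Both stay open, as does an effect of Kdm5b, which these tests do not separate from either.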

How the results depend on the processing

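The replicate block on the 6 control arrays was chosen after seeing the data; all other alternatives were planned. The ESC count of 979 became 2887 with array weights, 500 from its 6 arrays alone, 201 at a threshold of 0.01, 100 with a 2-fold minimum and 193 to 1536 without 1 array. The NPC count of 194 became 29 from its 6 arrays alone, 64 at 0.01, 69 with the 2-fold minimum and 83 to 220 without 1 array. The difference count of 267 became 152 with the replicate block, 955 with array weights, 18 at 0.01, 134 with the 2-fold minimum and 35 to 546 without 1 array. Control ESC replicate 1 and control NPC replicate 2 had the lowest array weights (0.386 and 0.395). The contrasts between states gave 2931 and 2754 with the 2-fold minimum and 8446 to 8965 and 8103 to 8497 without 1 array. The lists called, 6 in ESC, 13 in NPC, 12 for the difference, 14 in control and 11 in knockdown differentiation, became 0, 1, 0, 3 and 3 with an estimated correlation and 1, 4, 7, 24 and 20 with fry, and 3 in ESC with the filter on low values, which over all contrasts ended 7 list calls and added 3; without 1 array they ranged over 5 to 6, 10 to 16, 11 to 13, 13 to 16 and 10 to 12. The agreement of the knockdown effects between states ranged from -0.0530, its sign reversed, to 0.109, and the correlation of the NPC effect with the change between states from -0.502 to -0.401 in control and -0.314 to -0.158 in knockdown arrays. Fewer arrays and stricter thresholds explain part of these losses by construction, and otherwise the cause was not tested. Fits on 6 arrays also use only the spread of those arrays, and knockdown differentiation rose from 9164 to 10118 genes that way. Of the named gene calls, 15 were lost with the 6 arrays alone, 20 at 0.01, 3 with the 2-fold minimum, 2 with the intensity trend and robust prior, 3 with the replicate block and 81 over all fits without 1 array; 0 turned direction. With the replicate block, control differentiation had 9176 genes, and 8940 on the control arrays alone; ESC had 965 and NPC 174. The numbers were taken to pair the control arrays, which the difference also uses, and not the knockdown arrays. The block nevertheless gives all 4 groups the same replicate effects. Of 12 arrays, 8 matched their own number best in another group, a hint from the data. The block ended the difference calls of Dppa5a (adjusted p = 0.0556), Emcn (0.0585), Cdh5 (0.0510) and the endoderm list (0.0816) and added apoptosis in NPC (0.0359). Median centring moved the median gene of knockdown differentiation to -0.117. The deposited values come with no background measure, so what low signal limits could be checked only with the filter on low values.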

Other observations

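The splits with the common knockdown effect taken out, with and without the replicate numbers kept, were chosen after the other splits had been seen, and the genes with opposite changes after their values.

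Nodal, Boll, Ovol1 and Sqor passed the threshold in both states with opposite signs. These 4, lower in ESC and higher in NPC, are no more than independent lists would give (5.19). Nodal, a signalling ligand of early embryos, changed by -0.79 ± 0.15 in ESC and 0.74 ± 0.15 in NPC, and Boll, a germ cell RNA-binding protein of the Dazl family, by -0.89 ± 0.19 and 1.18 ± 0.19. Ovol1 changed by -0.56 ± 0.14 and 0.69 ± 0.14 and Sqor by -0.43 ± 0.11 and 0.53 ± 0.11 (SE, n = 3 arrays a group). Of the 154 genes that rose in knockdown NPC, 27 had a higher mean there than in knockdown ESC and 75 stayed at least 2-fold below control ESC. Stra8 was among the former, at 10.29 in knockdown NPC against 7.44 in knockdown ESC and 8.01 in control NPC.

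Other splits of the same arrays were tried. For knockdown in ESC 1 of 10 splits of the 6 arrays gave as many genes as the real 979, and the highest other gave 1; for knockdown in NPC it was 1 of 10, with 194 and 1. For control differentiation it was 1 of 10, with 9122 and 0, and for knockdown differentiation 1 of 10, with 9164 and 0. With 10 splits no share under 0.05 is possible. For the difference of the effects, 100 of 200 possible splits were drawn, and 2 of them, the real one with 267 genes included, gave as many. The other, with 554, exchanges the knockdown labels of 1 state and tests the sum of the effects, so this count says nothing on a difference between states. An earlier draw that was seen had missed that split. With the knockdown effect common to both states taken out of every probe set, 1 of the same 100 splits, the real one with 267, gave as many and the highest other gave 1. With only same-numbered arrays exchanged and the replicate block in the model it was 1 of 32, with 152 and 1. These counts set the real split apart, but the common effect was estimated with the real labels. That leaves the real difference untouched by construction, so chance between these arrays around an equal effect is not excluded. Chance between cultures stays open, since the labels do not say whether the arrays of a group are separate cultures, and without knockdown NPC replicate 2 the count was 35.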
